A study of Mus musculus with 6 samples.

How the data were processed

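RNA was taken from mouse SC4 cells 48 hours after transfection with a control siRNA or pooled YAP siRNA, 3 libraries per group. Per the labels' protocols, poly(A) RNA was fragmented to about 150 nt, ligated to directional adapters, amplified for 15 cycles and sequenced as paired-end barcoded libraries. Per the submitters' processing notes, TopHat2 2.0.9, HTSeq 0.6.1, DESeq 1.14.0 and the mouse build mm9 were used; the gene annotation, the strand setting of the counting and any filters are not given in the sources used here. How reads shared between a gene and its pseudogenes or paralogues were counted is also not given, so values of such genes are uncertain.

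The values the authors deposited are a signal unit, gene counts divided by 1 size factor per library, with 1 column per library. Each value above 0 was a whole multiple, within 0.01 reads, of what 1 read is worth in its library (100% of such values in each of the 6 libraries), so read counts were recovered. Size factors recomputed from them by the median-ratio method had a ratio of 1 to the deposited ones. Recovered reads ranged from 18025132 to 60078880 per library, so that 1 read was worth between 0.461 and 1.52 normalized counts. No 2 libraries of a group agreed within sampling noise: the chi-square of their counts per degree of freedom was between 8.23 and 293.

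Here, values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted), over genes with a mean of at least 10. The main design had no covariate. The 24 gene lists, each with at least 5 tested members, were tested with camera at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. The design, lists, naming rule and most other settings were set before the data were examined. The rule named 9 genes in advance; then, among genes past the threshold with a mean of at least 50, groups that do not overlap and a symbol that is not a numbered locus, the 10 with the largest rise and 10 with the largest fall; and in each list up to 3 passing members with the smallest p, or 1 where none passed. Because no gene passed in the main design, the last parts were also applied to the blocked fit, after the values were seen; Erbb3, Etv5, Spry1, Usp18, Ifi44 and Map2 were also named after their values were seen. A gene that the rule named is not reported here.

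The groups share replicate numbers in the labels. Deviations from the group means correlated across genes at 0.788, 0.705 and 0.532 for replicates 1, 2 and 3 of both groups, against −0.620, 0.552 and 0.516 for the best other number. Each was the higher, for replicate 3 by little, so by a criterion set beforehand the numbers were taken to pair the libraries. Deviations from a group mean cancel out, so with replicate 1 apart in both groups, replicates 2 and 3 can correlate with either number. The check therefore shows mainly a shared deviation of replicate 1, and tells replicate 2 from replicate 3 less clearly. The pairing comes from this check, not from a label that names a shared day or batch. The fit with the replicate number as a block, named beforehand as the other design, is given beside the main one.

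Alternatives were other pseudocounts (0.5, 10), filters (none, 50), scalings (one total, quantiles), variance models, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, stricter thresholds and leaving out libraries. The method was tested on simulated counts of 12820 genes with a known set changed. With the block, limma recovered 53.7% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 95.5% of those changed 4-fold, and 7.65% of its calls were false. Without the block it recovered 0%, 0% and 40.9%. The simulation gave unchanged genes the same mean in both groups for each replicate number and took dispersions from the blocked design. Changed genes had the same fold in all pairs. The advantage of the block was thus built in, and these rates need not hold where changes differ between pairs.

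Transcript GC content, 3' UTRs and sequence shared with pseudogenes (31-mers) were taken from GENCODE M21, built on another assembly than the files, so no coordinates are given; 22831 of 23366 genes matched a transcript, 1262 of them by an older symbol. In 10817 genes with a mean of at least 50 and a 3' UTR of at least 50 nt, each of 15638 7-mers was scored by the difference in log2 fold change between genes with and without it, as a z. The 7-mer with the lowest score and the one with the highest in the pair of replicate 1 were then measured in the other pairs.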

Results

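Gene expression was measured by RNA sequencing in SC4 cells, a mouse Schwann cell line derived from a schwannoma (a tumour of the nerve sheath) that lacks Nf2, the gene for the tumour suppressor merlin. Cells were transfected with a control siRNA or with a pool of siRNAs against YAP, a transcriptional co-activator encoded by Yap1 that the Hippo pathway restrains, and RNA was taken 48 hours later. Each group held 3 libraries, numbered 1 to 3. The labels do not say whether the 3 came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The deposited values were gene counts divided by a size factor for each library, and whole read counts could be recovered from them. The control libraries 1, 2 and 3 held 18821938, 35584397 and 60078880 reads in genes. The YAP siRNA libraries 1, 2 and 3 held 23289469, 26984156 and 18025132 reads. Of 23366 genes listed, 12820 with a mean normalized count of at least 10 were tested.

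The libraries separated first into replicate 1 against replicates 2 and 3, and then by siRNA. The first principal component held 63.5% of the variance and set replicate 1 of both groups apart from replicates 2 and 3, and the second held 23.1% and separated YAP siRNA from control siRNA. Across genes, the log2 values of control replicates 2 and 3 had a Pearson correlation of 0.988, and control replicates 1 and 2 of 0.917. It was 0.990 for YAP siRNA replicates 2 and 3, and 0.968 for replicate 2 of the control and of YAP siRNA. Replicate 2 was thus closer to replicate 3 of its own group than to the same number in the other.

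**Figure D1:**
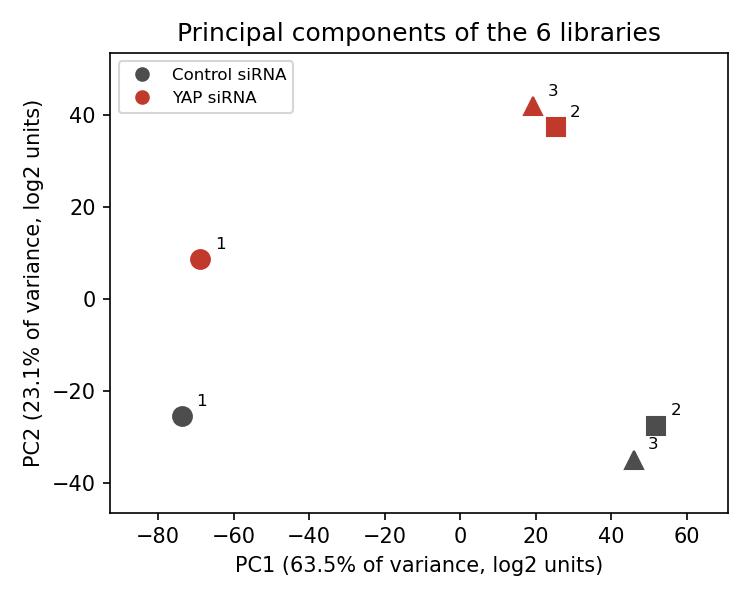
Principal components of log2(normalized count + 1) over the tested genes, with the first component on the x axis and the second on the y axis, each in log2 units. Each point is a library, colored by siRNA and numbered by replicate. Both replicate 1 libraries lie apart from the other 4 on the first component, which holds 63.5% of the variance.

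The target of the siRNA pool was lower in each library that received it. Yap1 had normalized counts of 4749.6, 5732 and 4751 in control replicates 1, 2 and 3, and of 936, 571 and 475 in YAP siRNA replicates 1, 2 and 3. The mean after YAP siRNA was 13.0% of the control mean. The log2 fold change was −3.00, on the log2(value + 1) scale used throughout, with limma adjusted p = 0.118 without pairing. With the replicate number as a block the SE was 0.184 and the adjusted p 4.5e-04, but the latter was 0.0604 in limma without a mean-variance trend. An exact permutation test, two-sided, gave p = 0.1, the smallest that 3 against 3 libraries can give. Without the block, limma adjusted p was 0.0262 without control replicate 1 and 0.0406 without YAP siRNA replicate 1.

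Without pairing, limma called 0 genes higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1558 genes, edgeR called 0 in either direction, and DESeq2 called 330 higher and 399 lower. Same-numbered libraries deviated together from their group means, replicate 1 most clearly. With the replicate number as a block limma called 1067 genes higher and 1149 lower. Of these, 190 and 287 differed at least 2-fold. The blocked calls fell to 12 higher and 18 lower in limma without a trend. Without replicate 2 of both groups they were 123 and 177, without replicate 3 538 and 590, and without replicate 1 2804 and 2792. With a pair left out, the blocked fit has few degrees of freedom of its own. Its p-values then rest largely on variances borrowed from other genes. Of 86 genes that were singled out and passed with the block, 41 lost their call without replicate 2, Areg, Ankrd1 and Nf2 among them, 10 without replicate 3, Nf2 among them, and 0 without replicate 1. Below, a gene is said to have risen or fallen, and is counted as higher or lower, only where it passed in the blocked fit; in limma and edgeR none of these genes passed without the block, and in DESeq2 without the block 719 of them did. Of 24 gene lists fixed before the data were examined, camera with a preset correlation called 7 without and 8 with the block, and camera with an estimated correlation called 0 and 0. By fry, which tests whether the genes of a list move one way on balance, 0 lists passed without and 0 with the block (smallest adjusted p 0.104 and 0.106), and 19 passed with the block for change in either direction.

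The series title names COX2 and EGFR, and some genes of both pathways were lower after YAP siRNA. Ptgs2, which encodes the prostaglandin-forming enzyme COX2, fell from 8546 ± 1342 to 1436 ± 623 normalized counts (SD, n = 3; log2 fold change −2.64, SE 0.241, limma adjusted p = 0.00127 with the block and 0.123 without). Over the alternative settings with the block, in limma, edgeR and DESeq2, its highest adjusted p was 0.0788, not past the threshold. The related gene Ptgs1 fell by 1.47 and the phospholipase Pla2g4a, which releases arachidonic acid, by 0.57 on the log2 scale. Without replicate 2 of both groups Pla2g4a did not pass (limma adjusted p = 0.166 with the block). Among prostaglandin synthesis, transport and receptor genes, 0 were higher and 4 lower of 14 tested, and 0 and 6 when adjusted over the list alone. The list was lower by camera (adjusted p = 9.5e-04 without and 0.00788 with the block), a call not held with an estimated correlation (adjusted p = 0.429 and 0.787 with an estimated correlation).

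Egfr itself had 2337 ± 249 normalized counts in the controls and 2189.7 ± 44.3 after YAP siRNA (SD, n = 3), a log2 fold change of −0.088 with a 95% interval of −0.32 to 0.15 with the block (limma adjusted p = 0.581). Several of its ligands fell. Areg, which encodes amphiregulin, went from 125 ± 37.3 to 22.8 ± 9.82 (SD, n = 3; log2 fold change −2.45, SE 0.397, limma adjusted p = 0.00661 with the block and 0.165 without). Hbegf fell by 1.20 and Btc fell by 1.65 on the log2 scale. The receptor gene Erbb3 rose, with a log2 fold change of 1.12. It did not pass without replicate 2 or without replicate 3 (limma adjusted p = 0.174 and 0.127 with the block). Over EGF family ligands, ERBB receptors and their regulators, 1 were higher and 8 lower of 15 tested, and 1 and 8 when adjusted over the list alone. The list was lower by camera (adjusted p = 0.00324 without and 0.0272 with the block), but not with an estimated correlation (adjusted p = 0.429 and 0.787 with an estimated correlation). It did not pass when genes sharing sequence with pseudogenes were left out (adjusted p = 0.0566) or when genes whose 3' UTR carries the 7-mer CTACATA or one overlapping it were left out (adjusted p = 0.430), nor with the block when replicate 2 of both groups was left out (adjusted p = 0.0867). These 7-mers were chosen in the same data because their carriers were lower, so leaving carriers out tends to weaken a list that is lower. Ptgs2, Hbegf, Btc and Egfr carry CTACATA in their annotated 3' UTRs, as do the named genes Nf2, Amot, Tead1, F3, Vegfa, P4ha1, Tpm2, Kcnmb2 and Etv5; carriers as a class were lower, as given in the closing observations.

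Some genes induced by ERK signalling fell. The phosphatase gene Dusp5 fell from 2371 ± 1071 to 884 ± 379 normalized counts (SD, n = 3; log2 fold change −1.41, SE 0.105, limma adjusted p = 7.3e-04 with the block). Spred3 fell by 1.36, Ier3 fell by 1.16 and the transcription factor gene Etv5 by 1.86 on the log2 scale, whereas the feedback inhibitor gene Spry1 rose by 1.23. Etv5 shares 32.3% of its 31-mers with annotated pseudogenes. In this list 1 were higher and 10 lower of 20 tested, and 2 and 11 when adjusted over the list alone. Camera placed it lower (adjusted p = 0.00283 without and 0.0133 with the block), with adjusted p = 0.429 and 0.787 with an estimated correlation and 0.0501 with the block when genes sharing sequence with pseudogenes were left out.

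Genes often used as YAP targets did not move as a set. Ctgf had 12784 ± 1466 normalized counts in the controls and 12921 ± 3432 after YAP siRNA (SD, n = 3; limma adjusted p = 0.934 with the block), and its log2 fold change of −0.017 turned above 0 when libraries were rescaled to one total. Cyr61 had a log2 fold change of 0.24 (limma adjusted p = 0.196 with the block). It passed as higher without replicate 1 of both groups, at 0.43 (limma adjusted p = 1.1e-06 with the block and 0.00454 without). With few libraries left, the blocked value rests largely on variance borrowed from other genes. Ankrd1 rose from 3415 ± 967 to 5088 ± 486 (SD, n = 3; log2 fold change 0.61, SE 0.119, limma adjusted p = 0.0126 with the block). Amotl2 and Rbms3 rose by 0.83 and 0.94, and F3, which encodes tissue factor, fell by 0.90 on the log2 scale. In the target list 5 were higher and 4 lower of 22 tested, and 6 and 5 when adjusted over the list alone, and camera gave adjusted p = 0.810 without and 0.937 with the block.

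**Figure D2:**
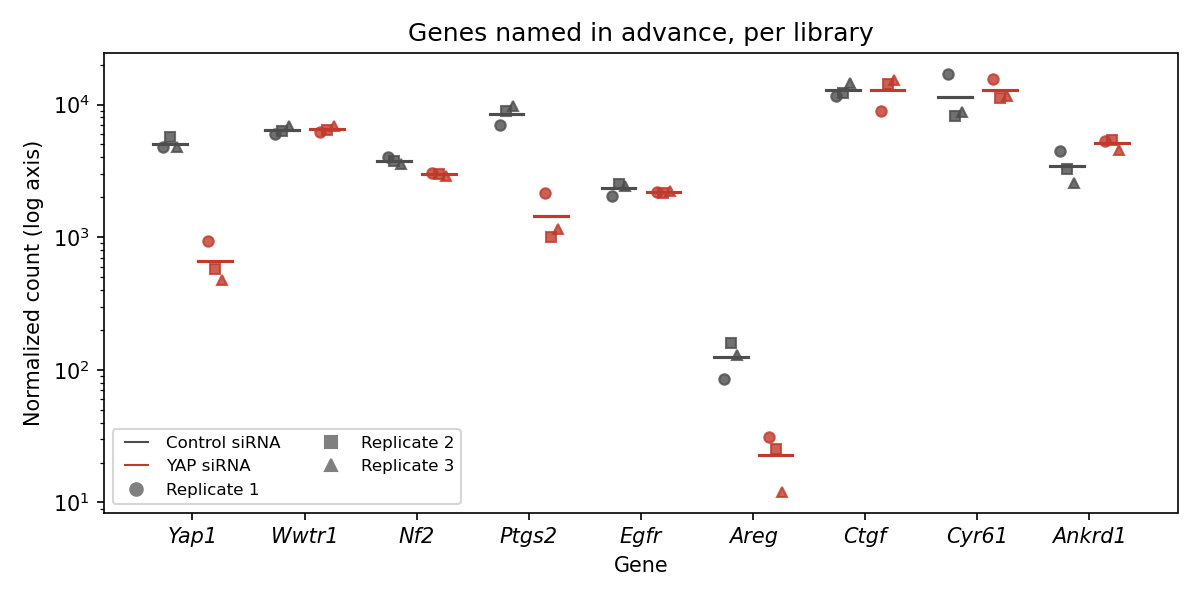
Normalized counts on a log axis (y) of the 9 genes named in advance (x). Points are libraries, shaped by replicate and colored by siRNA, and bars are group means. Yap1, Ptgs2 and Areg lie lower in all 3 YAP siRNA libraries than in all 3 controls, and the groups overlap for Wwtr1, Egfr, Ctgf and Cyr61.

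Within the Hippo pathway, Wwtr1, which encodes the YAP paralogue TAZ, had a log2 fold change of 0.025 with a 95% interval of −0.16 to 0.21 with the block. The transcription factor gene Tead1 rose from 5083 ± 291 to 10379 ± 957 normalized counts (SD, n = 3), and the scaffold gene Amot fell by 1.17 on the log2 scale. Reads were counted for Nf2 at 3779 ± 215 in the controls and 2985 ± 89.3 after YAP siRNA (SD, n = 3; limma adjusted p = 0.0317 with the block); these gene-level values do not show which exons the reads came from. Of Hippo pathway genes, 6 were higher and 7 lower of 29 tested, and 8 and 8 when adjusted over the list alone (camera adjusted p = 0.774 without and 0.937 with the block). Yap1 itself, the target of the siRNA pool, is counted among the lower genes of this list.

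Genes of G2 and mitosis that passed were all higher. Cenpf, which encodes a kinetochore protein, rose from 7852 ± 3061 to 14489 ± 1181 (SD, n = 3; log2 fold change 0.95, SE 0.149, limma adjusted p = 0.00602 with the block). Nusap1 rose by 0.87 and the mitotic kinesin gene Kif11 by 0.67 on the log2 scale. Of the G2 and mitosis genes, 13 were higher and 0 lower of 26 tested, and 20 and 0 when adjusted over the list alone. Camera placed the list higher (adjusted p = 0.00495 without and 4.9e-06 with the block), with adjusted p = 0.981 and 0.787 with an estimated correlation. Without the block, the camera adjusted p rose to 0.320 without YAP siRNA replicate 1, 0.177 without control replicate 3 and 0.0513 without control replicate 2. In the S phase list 1 were higher and 1 lower of 28 tested, and 1 and 1 when adjusted over the list alone; Pola1 rose by 0.54 and the cyclin gene Ccne1 fell by 1.11 on the log2 scale, with camera adjusted p = 0.916 without and 0.937 with the block. Without YAP siRNA replicate 1 and without the block, the S phase list was lower (adjusted p = 0.0413), where an estimated correlation with all libraries gave 0.981.

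Matrix genes that passed were lower and higher. The matrix metalloproteinase gene Mmp3 fell from 1252 ± 620.0 to 178 ± 39.5 normalized counts and Sparc from 160307 ± 48737 to 89470.0 ± 13543, while Timp3, which encodes a metalloproteinase inhibitor, rose from 18505 ± 856 to 31724 ± 3934 (SD, n = 3 for each). The log2 fold change of Mmp3 was −2.66, and −3.36 without replicate 1 of both groups. In this list 3 were higher and 10 lower of 33 tested, and 3 and 14 when adjusted over the list alone. Camera placed it lower (adjusted p = 0.0202 without and 0.00864 with the block), with adjusted p = 0.981 and 0.787 with an estimated correlation; without YAP siRNA replicate 1 and without the block the adjusted p was 0.715. Without the block it was 0.303 without control replicate 2 and 0.200 without control replicate 3. With the block it was 0.0501 when genes sharing sequence with pseudogenes were left out.

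Contractile, TGF-beta and growth factor genes went both ways. Among actin and SRF target genes 6 were higher and 3 lower of 24 tested, and 7 and 5 when adjusted over the list alone; the smooth muscle actin gene Acta2 and Cnn2 rose by 2.72 and 0.65, and the integrin gene Itga5 and Tpm2 fell by 0.87 and 1.96 on the log2 scale (camera adjusted p = 0.340 without and 0.387 with the block). Acta2 was at 3.86 without replicate 1 of both groups and at 1.96, not past the threshold, without replicate 2. Among TGF-beta and BMP pathway genes 5 were higher and 5 lower of 22 tested, and 5 and 7 when adjusted over the list alone, with Id3 up by 1.43, Tgfbr3 up by 0.68 and Tgfbi with a log2 fold change of −0.54 (camera adjusted p = 0.916 without and 0.937 with the block). Among other growth factors and receptor tyrosine kinases 2 were higher and 9 lower of 25 tested, and 6 and 13 when adjusted over the list alone, with log2 fold changes of −3.59 for the MET ligand gene Hgf, −1.15 for Vegfa and 0.98 for Pdgfrb (camera adjusted p = 0.0604 without and 0.105 with the block). Without the block, camera adjusted p was 0.0140 for the growth factor list without control replicate 1, 0.0246 without YAP siRNA replicate 2, and 0.0413 for the actin and SRF list without YAP siRNA replicate 1. The growth factor list also passed with edgeR (0.0372 without and 0.0171 with the block) and DESeq2 (0.0412 and 0.0260). With an estimated correlation and all libraries in limma, adjusted p was 0.981 without and 0.787 with the block for the growth factor list, and 0.981 without and 0.961 with the block for the actin and SRF list.

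**Figure D3:**
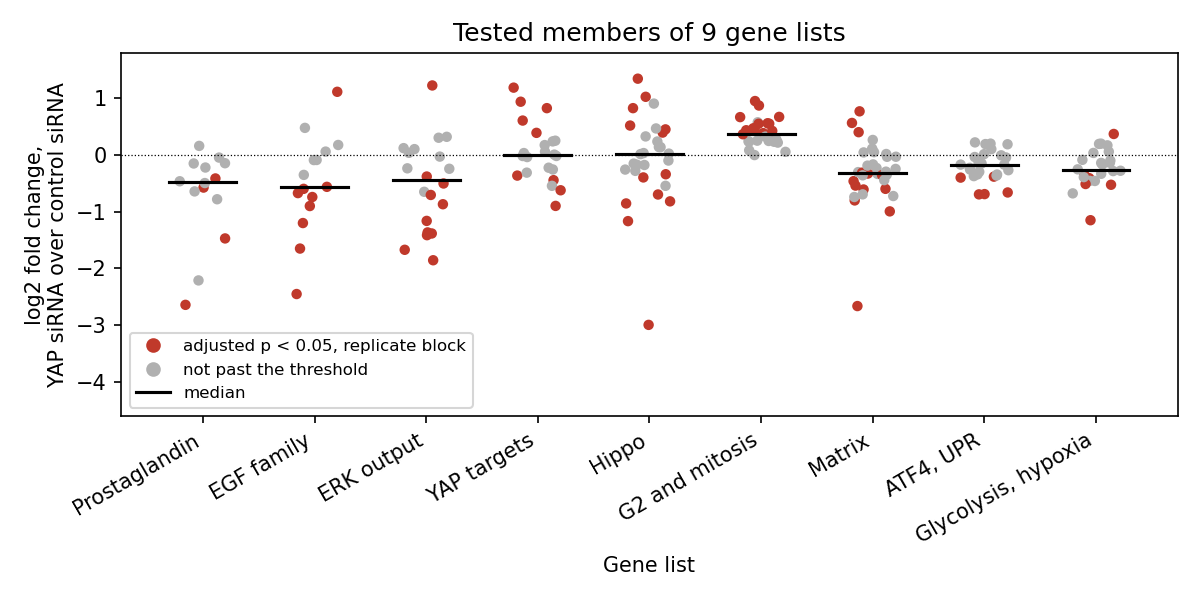
Log2 fold change after YAP siRNA over control siRNA (y) of the tested members of 9 gene lists (x). Each point is a gene, red where the adjusted p was under 0.05 with the replicate block and grey otherwise, and black bars are list medians. The median of the prostaglandin list is −0.48 and that of the G2 and mitosis list is 0.38.

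Stress and metabolic lists were tested in the same way. In the ATF4 and unfolded protein response list 0 were higher and 5 lower of 27 tested, and 0 and 5 when adjusted over the list alone; Ddit3, a stress-induced transcription factor gene, fell by 0.66, Vldlr by 0.69 and Creld2 by 0.40 on the log2 scale. Camera placed it lower (adjusted p = 0.0179 without and 0.0235 with the block), with adjusted p = 0.429 and 0.787 with an estimated correlation; with replicate 1 of both groups left out the adjusted p was 0.138. Without the block it was 0.125 without control replicate 1 and 0.0943 without YAP siRNA replicate 3. Among glycolysis and hypoxia genes 1 were higher and 5 lower of 24 tested, and 1 and 8 when adjusted over the list alone, Pfkp and P4ha1 with log2 fold changes of −0.52 and −0.51; camera passed with the block (adjusted p = 0.0604 without and 0.0255 with the block), with adjusted p = 0.429 and 0.787 with an estimated correlation. With the block, when genes sharing sequence with pseudogenes were left out, camera adjusted p was 0.0566 for the ATF4 list and 0.0818 for glycolysis and hypoxia, and when genes with an enriched 7-mer were left out 0.0874 and 0.158. Those 7-mers were chosen for lower carriers, so leaving carriers out tends to weaken lists that are lower. Among p53 targets 1 were higher and 2 lower of 21 tested, and 1 and 2 when adjusted over the list alone; the cell cycle inhibitor gene Cdkn1a fell from 3976 ± 779 to 2058 ± 325 normalized counts (SD, n = 3), Mdm2 fell by 0.43 and the death receptor gene Fas rose by 1.77 on the log2 scale (camera adjusted p = 0.774 without and 0.937 with the block). Among apoptosis regulators 2 were higher and 2 lower of 27 tested, and 2 and 2 when adjusted over the list alone, Bcl2l2 with a log2 fold change of −0.50 (camera adjusted p = 0.916 without and 0.937 with the block). Among sterol and fatty acid synthesis genes 1 were higher and 0 lower of 26 tested, and 0 and 0 when adjusted over the list alone, Scd2 with a log2 fold change of 0.39 (camera adjusted p = 0.774 without and 0.604 with the block). Leaving out single libraries or pairs also moved calls in these lists: camera adjusted p was 0.134 for the ATF4 list with the block without replicate 1, 0.0723 for glycolysis and hypoxia with the block without replicate 3, and, without the block, 0.0228 without control replicate 2 and 0.0153 without YAP siRNA replicate 1. The sterol list was higher without control replicate 1 and without the block (0.0430), where an estimated correlation with all libraries gave 0.981. Without the block, it turned lower without control replicate 2, control replicate 3 or YAP siRNA replicate 1, short of the threshold (0.929, 0.833 and 0.772).

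Interferon response genes went both ways. Cxcl10, Gbp2 and Ccl5 rose by 1.29, 1.30 and 1.70 and Ifit2 by 0.58 on the log2 scale, and Usp18 and Ifi44 fell by 1.86 and 1.84. Without replicate 1 of both groups the log2 fold change of Ifi44 was −2.45. Without replicate 2, Usp18, Ifi44, Ccl5 and Ifit2 did not pass (limma adjusted p = 0.111, 0.295, 0.0839 and 0.0698 with the block). Usp18 and Ifi44 also did not pass without replicate 3 (limma adjusted p = 0.0644 and 0.0675 with the block). In this list 6 were higher and 2 lower of 34 tested, and 9 and 2 when adjusted over the list alone (camera adjusted p = 0.340 without and 0.186 with the block). The list was higher by camera without the block when control replicate 2, control replicate 3 or YAP siRNA replicate 1 was left out (adjusted p = 0.0132, 0.0154 and 0.0113), and with the block without replicate 2 (adjusted p = 0.0109). Short of the threshold, it turned lower by camera without control replicate 1 and without the block (adjusted p = 0.117). It also did so with the block without replicate 1 (adjusted p = 0.861). An estimated correlation with all libraries gave adjusted p = 0.981 without and 0.961 with the block. Among NF-kappaB target, cytokine and chemokine genes 3 were higher and 3 lower of 21 tested, and 3 and 3 when adjusted over the list alone; the cytokine gene Lif fell from 1094 ± 369.8 to 306 ± 30.8 normalized counts (SD, n = 3), and Cxcl12 and Tnfaip3 rose by 1.24 and 0.89 on the log2 scale (camera adjusted p = 0.916 without and 0.937 with the block). Among Schwann cell and myelin genes 4 were higher and 3 lower of 18 tested, and 4 and 3 when adjusted over the list alone; Fabp7 rose from 14.9 ± 2.83 to 73.3 ± 2.43 (SD, n = 3), the myelin gene Pmp22 had a log2 fold change of 1.00 and Ngfr of −0.80 (camera adjusted p = 0.136 without and 0.186 with the block). The Schwann list was higher without the block when control replicate 3 or YAP siRNA replicate 1 was left out (adjusted p = 0.0316 and 0.0328), and with an estimated correlation and all libraries had adjusted p = 0.981 without and 0.787 with the block.

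Markers of other cell types and of RNA quality were measured beside these groups. The keratin genes Krt18, Krt19 and Krt8 fell, with log2 fold changes of −2.32, −1.92 and −1.89, and the neuronal marker Map2 rose by 1.12 on the log2 scale. Krt8 and Krt18 share 32.2% and 11.4% of their 31-mers with annotated pseudogenes. Of epithelial and neuronal markers 1 were higher and 3 lower of 7 tested, and 1 and 3 when adjusted over the list alone. Camera placed this list lower (adjusted p = 0.0157 without and 0.0241 with the block), with adjusted p = 0.870 and 0.787 with an estimated correlation and 0.423 without and 0.292 with the block when low genes were kept. With the block it was 0.389 when genes sharing sequence with pseudogenes were left out. Without YAP siRNA replicate 1 and without the block it was 0.0812. Among macrophage and leukocyte markers 0 were higher and 2 lower of 6 tested, and 1 and 2 when adjusted over the list alone, Csf1r from 161 ± 38.6 to 76.2 ± 11.9 and Cd74 from 1626 ± 1366 to 168 ± 111 (SD, n = 3 for each; camera adjusted p = 0.774 without and 0.937 with the block). The log2 fold change of Cd74 was −2.41, and −3.41 without replicate 1 of both groups. Without replicate 2 Cd74 was at −1.84 and did not pass (limma adjusted p = 0.101 with the block). Csf1r did not pass without replicate 2 or without replicate 3 (limma adjusted p = 0.229 and 0.0888 with the block). Among fibroblast markers 2 were higher and 3 lower of 13 tested, and 3 and 4 when adjusted over the list alone, with log2 fold changes of 1.53 for Dpt and −0.46 for Col1a1 (camera adjusted p = 0.518 without and 0.937 with the block), and adjusted p = 0.0426 without YAP siRNA replicate 1 and without the block, where an estimated correlation with all libraries gave 0.981. Among endothelial markers 0 were higher and 0 lower of 6 tested, and 0 and 0 when adjusted over the list alone; Flt1, with the smallest p, had a log2 fold change of −0.38 and passed with the block without replicate 1 and in DESeq2 (camera adjusted p = 0.980 without and 0.937 with the block). Of the RNA quality list, whose mitochondrially encoded members were not analysed here, 1 were higher and 0 lower of 10 tested, and 1 and 0 when adjusted over the list alone; the nuclear RNA Neat1 rose from 6152 ± 420.4 to 13023 ± 4729 (SD, n = 3; camera adjusted p = 0.518 without and 0.232 with the block).

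The rule for naming the genes with the greatest changes, fixed before the data were examined, named none without the block. The same rule applied to the blocked fit, a choice made after the values were seen, gave 10 genes in each direction. Among those that fell, Dmp1 went from 247 ± 206 to 4.03 ± 3.49 normalized counts, the urea transporter gene Slc14a1 from 119.6 ± 27.4 to 10.7 ± 7.39, the ceruloplasmin gene Cp from 1247 ± 970.4 to 76.1 ± 32.7, Mmp10 from 592 ± 286 to 57.3 ± 7.78 and the semaphorin gene Sema7a from 8998 ± 2156 to 1432 ± 206 (SD, n = 3 for each), beside Yap1, Ptgs2, Hgf, Mmp3 and Tns4 (−2.75 log2). Among those that rose, the small proteoglycan gene Fmod went from 30.4 ± 18.6 to 574 ± 451, the retinal dehydrogenase gene Aldh1a1 from 130.0 ± 55.6 to 1319 ± 576, Kctd12 from 57.1 ± 16.2 to 482 ± 226, Wisp2 from 139 ± 74.7 to 843 ± 473 and Rgs4 from 191 ± 27.8 to 856 ± 189 (SD, n = 3 for each). Acta2, Cyp1b1, Kcnmb2, Coch and Serpina3f had log2 fold changes of 2.72, 2.32, 2.27, 2.21 and 2.07. Without replicate 1 of both groups, log2 fold changes went from −4.91 to −5.70 for Dmp1, −3.42 to −4.23 for Cp, −3.20 to −3.81 for Mmp10, 3.71 to 4.47 for Fmod, 3.30 to 4.05 for Aldh1a1, 2.96 to 3.62 for Kctd12 and 2.27 to 3.07 for Kcnmb2. Without replicate 2, Coch was at 1.48 and did not pass. Serpina3f shares 14.2% of its 31-mers with annotated pseudogenes. Over all tested genes, 1214 were higher and 1216 lower in every YAP siRNA library than in every control, or 19.0% of genes. Chance would give 10% if the 6 libraries were exchangeable, which same-numbered libraries, deviating together, are not, so that the share by chance is not known here.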

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

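The counts of genes depended on the pairing, on the variance model and on single libraries. Against 0 higher and 0 lower without the block, the replicate block gave 1067 and 1149 and DESeq2 330 and 399. Chosen after seeing the data, replicate 1 as a batch gave 1201 and 1291, and leaving out replicate 1 of both groups gave 1912 and 2106. Leaving out each library in turn without the block gave 0 to 192 higher and 0 to 305 lower, the highest without control replicate 1. With the block, which was run with the other settings after seeing the data, the counts of 1067 and 1149 became 12 and 18 without a trend, 262 and 357 at an adjusted p under 0.01, 190 and 287 at 2-fold or more, and 123 to 2804 and 177 to 2792 without 1 pair. The lowest was without replicate 2 and the highest without replicate 1. Without genes carrying an enriched 7-mer, 779 were higher and 746 lower. This tests fewer genes, and the 7-mers were chosen in the same data because their carriers were lower. Other pseudocounts, filters, scalings and tools stayed within 1.5 times the blocked counts; edgeR with the block called 1190 higher and 1289 lower.

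Yap1 passed with the block (−3.00), in DESeq2 (−2.94), with replicate 1 as a batch (−3.00) and with replicate 1 left out (−3.32), all log2, and lost its call with the block without a trend (−3.00). Leaving out each library gave −3.28 to −2.79. Of the other named genes, only Ctgf and Wwtr1 changed sign, neither past the threshold. Ctgf was 0.014 in DESeq2, 0.017 in edgeR, 0.011 at one total with or without the block, 0.16 without replicate 1, −0.16 to 0.22 without single libraries and −0.14 to 0.16 without single pairs. Wwtr1 was −0.034 with the GC correction and −0.016 to 0.075 without single libraries. Over all named genes and settings, 360 values gained a call against the unpaired fit and 138 lost one against the blocked fit. Another 3 values gained a call against the blocked fit, for Cyr61 without replicate 1, and for Flt1 without replicate 1 and in DESeq2.

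No list call held with an estimated correlation. Camera adjusted p-values were then prostaglandin 0.429, EGF family 0.429, ERK output 0.429, G2 and mitosis 0.981, matrix 0.981, ATF4 0.429, epithelial and neuronal 0.870 without the block, and prostaglandin 0.787, EGF family 0.787, ERK output 0.787, G2 and mitosis 0.787, matrix 0.787, ATF4 0.787, glycolysis and hypoxia 0.787, epithelial and neuronal 0.787 with it. Other calls were lost as follows. ATF4 had adjusted p of 0.138 with replicate 1 of both groups left out. Epithelial and neuronal had adjusted p of 0.423 with no filter on low values. EGF family, ERK output, matrix, ATF4, glycolysis and hypoxia and epithelial and neuronal had adjusted p of 0.0566, 0.0501, 0.0501, 0.0566, 0.0818 and 0.389 with the block and genes sharing sequence with pseudogenes left out. EGF family, ATF4 and glycolysis and hypoxia had adjusted p of 0.430, 0.0874 and 0.158 with the block and genes with an enriched 7-mer left out. Choosing the 7-mers for lower carriers in the same data tends to weaken lower lists in this setting. Epithelial and neuronal had adjusted p of 0.292 with the block and no filter on low values. Calls were gained as follows. Growth factor had adjusted p of 0.0372 with edgeR on recovered reads. Growth factor had adjusted p of 0.0412 with DESeq2 on recovered reads. Glycolysis and hypoxia had adjusted p of 0.0255 with the block. Glycolysis and hypoxia had adjusted p of 0.0357 with replicate 1 of both groups as a batch. Growth factor had adjusted p of 0.0171 with the block and edgeR on recovered reads. Growth factor had adjusted p of 0.0260 with the block and DESeq2 on recovered reads. Lists changed direction, as follows; without YAP siRNA replicate 1 and without the block the S phase list did so past the threshold (0.0413), the others short of it. S phase, TGF-beta, NF-kappaB and cytokine and fibroblast had adjusted p of 0.937, 0.937, 0.937 and 0.937 with the block. S phase, TGF-beta, interferon, p53 and endothelial had adjusted p of 0.876, 0.876, 0.876, 0.876 and 0.876 with replicate 1 of both groups left out. TGF-beta, NF-kappaB and cytokine and fibroblast had adjusted p of 0.973, 0.973 and 0.973 with replicate 1 of both groups as a batch. NF-kappaB and cytokine had adjusted p of 0.910 with a mean value of at least 50. Endothelial had adjusted p of 0.973 with a pseudocount of 10. Endothelial had adjusted p of 0.989 with no filter on low values. Endothelial had adjusted p of 0.791 with edgeR on recovered reads. Endothelial had adjusted p of 0.806 with DESeq2 on recovered reads. Hippo, TGF-beta and macrophage had adjusted p of 0.989, 0.989 and 0.891 with the block and genes with an enriched 7-mer left out. S phase and fibroblast had adjusted p of 0.953 and 0.995 with the block and no filter on low values. S phase had adjusted p of 0.951 with the block and libraries rescaled to one total. S phase, NF-kappaB and cytokine, fibroblast and endothelial had adjusted p of 0.959, 0.959, 0.817 and 0.938 with the block and edgeR on recovered reads. S phase, NF-kappaB and cytokine, fibroblast and endothelial had adjusted p of 0.996, 0.905, 0.568 and 0.905 with the block and DESeq2 on recovered reads. S phase had adjusted p of 0.914 with the block and genes sharing sequence with pseudogenes left out. Fibroblast had adjusted p of 0.958 with the block and a mean value of at least 50. Fibroblast had adjusted p of 0.936 with the block and quantile normalization. Fibroblast had adjusted p of 0.981 with the block and GC correction. Leaving out single libraries without the block gave adjusted p from the lower to the higher value of YAP targets 0.304 to 0.946, Hippo 0.477 to 0.944, S phase 0.0413 to 0.834, G2 and mitosis 4.7e-06 to 0.320, actin and SRF 0.0413 to 0.561, matrix 1.2e-04 to 0.715, TGF-beta 0.421 to 0.965, growth factor 0.0140 to 0.293, Schwann 0.0316 to 0.740, interferon 0.0113 to 0.908, NF-kappaB and cytokine 0.216 to 0.910, apoptosis 0.715 to 0.946, p53 0.498 to 0.848, sterol 0.0430 to 0.929, ATF4 0.00433 to 0.125, glycolysis and hypoxia 0.0153 to 0.269, fibroblast 0.0426 to 0.933, macrophage 0.249 to 0.944, endothelial 0.622 to 0.946, epithelial and neuronal 0.00415 to 0.0812. Leaving out single pairs with the block gave YAP targets 0.861 to 0.995, EGF family 0.0152 to 0.0867, S phase 0.861 to 0.966, interferon 0.0109 to 0.861, NF-kappaB and cytokine 0.882 to 0.966, p53 0.661 to 0.863, ATF4 0.0152 to 0.134, glycolysis and hypoxia 0.0157 to 0.0723, fibroblast 0.835 to 0.986, macrophage 0.347 to 0.966, endothelial 0.421 to 0.995. Alternatives with replicate 1 as a batch or left out, and all with the block beyond the block itself, were chosen after seeing the data. For all these changes the cause was not tested.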

Other observations

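The tests of splits with the block, GC content, depth and base composition, and the reverse choice of 7-mers, were written after related results had been seen. Certain 7-mers were first noticed over all 3 pairs, and the choice in the pair of replicate 1 alone was made afterwards. The tests of Wwtr1, interferon genes and unpaired splits were written before the data were examined. Those of pseudogene sequence and of 7-mers upstream of the 3' UTR were written after the patterns were seen, before the deciding value was.

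Hgf, which encodes the ligand of the receptor MET, and Lif fell together with EGF family ligands, with log2 fold changes of −3.59 and −1.77. In the pair of replicate 1 the changes were −3.18 and −1.31, in the pair of replicate 2 −3.66 and −2.07, and in the pair of replicate 3 −3.94 and −1.94. Of 4018 genes called in replicates 2 and 3 alone, 79.7% changed in the same direction in the pair of replicate 1, against 60.0% of other genes. Their changes in the pair of replicate 1 were a median of 0.338 times the mean change of the other pairs, which was also used to call them.

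With 3 against 3 libraries the splits are too few to give a share under 0.05. Without the block the real split gave 0 genes and the highest other split 0, and 10 of 10 splits gave as many. With the block the real split gave 2216 genes and the highest of the others that part all 3 pairs 0; 1 of 4 gave as many. Each of these others exchanges the groups of the libraries of 1 pair.

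Replicate 1 of both groups stood apart from replicates 2 and 3. Genes sharing over 50% of their 31-mers with annotated pseudogenes were higher in replicate 1 by 1.58 on the log2 scale on average, against −0.25 for genes sharing none, but without genes sharing at least 1% the SD of the difference across genes stayed at 85.5% of its value, which argues against shared reads as the whole cause. A trend on transcript GC took 8.87% of the variance, which argues against GC as the whole cause. The library with the fewest reads, about 18025100, was YAP siRNA replicate 3, which argues against depth as the whole cause. That rests on 1 library, since the other libraries of replicates 2 and 3 held more reads than both of replicate 1. A difference in culture, library preparation or alignment stays open as untested, since the labels name no batch; no biological explanation was tested.

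Genes with certain 7-mers in their 3' UTRs were lower after YAP siRNA. The z values and 95% intervals of 7-mers are over genes, taken as independent, and do not hold the spread between libraries. Among 10817 genes, CTACATA was the 7-mer with the lowest score in the pair of replicate 1. In the pairs of replicates 2 and 3 its carriers differed from other genes by −0.16 on the log2 scale (95% interval −0.19 to −0.12). Genes with it upstream of the 3' UTR and not in it differed by −0.026 (−0.074 to 0.022). It was carried by 17.3% of genes lower with the block, 8.52% of those higher and 9.58% of the rest. The calls behind these shares used all pairs, including the one in which the 7-mer was chosen. Unlike the differences, the shares were not adjusted for 3' UTR length and GC content. They are thus no separate support. In the pairs of replicates 2 and 3 its z was −9.43. Rearrangements of its letters that share 5 letters in a row with it, such as TACATAC at −5.90, were left out of the comparison. The lowest of the remaining rearrangements was at −4.39, which argues against base composition. These values are consistent with seed matches of an siRNA of the YAP pool, or of a microRNA that changed, as a hypothesis; the siRNA sequences are not given in the sources used here, and each preparation was used in 1 group only, so part of the fall of carriers such as Ptgs2, Hbegf and Btc may not depend on YAP. Other 7-mers also had a low z in the pairs of replicates 2 and 3, such as TATTTAT at −9.80. Whether carriers of CTACATA were lower apart from those was not tested. A 7-mer of rises chosen in the same way, CACATCA, did not carry over. Its difference in the pairs of replicates 2 and 3 was 0.0083 (95% interval −0.023 to 0.040) in the 3' UTR and −0.010 upstream. Its z for the 3' UTR in these pairs, 0.510, lay below the 1.59 of the highest rearrangement, with the same kind left out.

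In a second attempt with the choice reversed, the leading 7-mers in the pairs of replicates 2 and 3 were TATTTAT for falls (−0.10 (95% interval −0.13 to −0.083) there and −0.034 (95% interval −0.050 to −0.019) in the pair of replicate 1) and AAGCCTT for rises (0.14 (95% interval 0.11 to 0.16) and 0.050 (95% interval 0.031 to 0.068)). In the pair of replicate 1, genes with the 7-mer only upstream of the 3' UTR differed by −0.027 (95% interval −0.065 to 0.010) for TATTTAT, reaching its value in the 3' UTR, and by 0.017 (95% interval −0.0021 to 0.036) for AAGCCTT. The leading 7-mers of both falls and rises differed between the 2 choices, though by rank CTACATA was number 2 from the lowest in the pairs of replicates 2 and 3 and AAGCCTT number 3 from the highest in the pair of replicate 1. No explanation is offered for those of the reversed choice.

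With all libraries Ctgf and Cyr61 did not pass and Ankrd1 rose, where Yap1 was at 13.0% of its control mean. Without replicate 1 of both groups Cyr61 also passed as higher, though with few libraries left. A lower level of the paralogue is not seen beside this: the 95% interval of the log2 fold change of Wwtr1 without the block began at −0.255. Whether TAZ kept these genes at their level was not tested. The mean log2 fold change of the 34 tested interferon response genes was 0.163 with a 95% interval of −0.10 to 0.42. This interval is over genes, taken as independent, and is too wide to exclude a difference between the siRNA preparations.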
